A study of Mus musculus with 16 samples.

How the data were processed

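Gene expression and hashtag libraries of sorted mouse brain immune cells were read from the deposited matrices, 8 libraries of each kind. The 3 gene expression libraries of 2 weeks are called A, B and C. Per the submitters' processing notes the reads were processed with Cell Ranger 7 against mm10, and per the file headers the software version was 7.0.0. The values are counts, the number of distinct UMIs per gene or hashtag and cell, as deposited. The gene annotation release used by the authors is not given in the sources used here. All deposited columns were used. The table of hashtags deposited with the series lists a genotype and a sex for the hashtags of E16, 1, 2, 4 and 6 weeks and has no entry for 3 weeks. Xist and Y-linked RNA of each labelled pool were checked against the listed sex, and no pool contradicted it.

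Cells were kept with at least 500 genes, at least 1000 UMIs and under 10% mitochondrial UMIs, and 43750 cells passed. Hashtag counts were transformed by centered log ratios per library and each hashtag was split with a 2-component Gaussian mixture. Cells positive for exactly 1 hashtag (31202) were used, cells positive for several were left out as doublets, and cells positive for none were left out. Several hashtags were found in 32.6% of cells at E16, 5.20% at 1 week, 6.00% in library C of 2 weeks, 8.96% at 3 weeks, 22.9% at 4 weeks and 17.2% at 6 weeks. Libraries A and B of 2 weeks had 1 listed hashtag each, so doublets cannot be seen there by hashtag. In these libraries 59.7% and 30.0% of cells had no hashtag. A rule that takes the largest hashtag gave 32955 cells, and the 30793 cells assigned by both rules had the same hashtag. Scrublet scores were computed per library as an alternative. They marked 0 cells at 3, 4 and 6 weeks, where they cannot be taken as a count of doublets, and 4.44, 4.17 and 3.90% in the libraries of 2 weeks.

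Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, without receptor segments, mitochondrial, ribosomal, hemoglobin and sex-linked genes, gave 30 principal components and a graph of 15 neighbors. Leiden clustering at resolution 1.0 gave 34 clusters, with no integration of libraries. Clusters were named, with the ending "-like", from fixed marker lists, and a cluster whose scores for more than 1 cell type were close was left unnamed. Doublets within 1 pool remain possible. Analyses in Python 3.11.15 used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2 and matplotlib 3.10.9.

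Counts were summed per class and pool (at least 10 cells) for genotype and per class and library (at least 20 cells) for age. Both were tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test) and limma 3.58.1, and as an alternative with DESeq2 1.42.0. The Benjamini-Hochberg adjustment was made over genes within a class, and an adjusted p under 0.05 passed. The standard error of a log2 change was taken as the change divided by the square root of its F value. For age the slope on log2 weeks over the 7 postnatal libraries was tested. The library was the unit because each age but 2 weeks is 1 library. For genotype the library was a covariate. The duplicated interval was tested on sums over all lymphoid cells of pools with at least 50 such cells. Single ages were tested with contrasts of 1 fit with age-by-genotype groups, and genotype by age with the joint test of its interaction terms. The hashtags mark pools and not single animals, so the pool stands in for the animal.

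Shares of classes were taken among sorted lymphoid cells. Age was tested by permuting the pairing of 7 libraries and ages in every way, and genotype by permuting labels within libraries, with pools of at least 50 assigned cells. Binomial and Poisson intervals are exact, at 95%. Fixed gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over lists within a fit. Of 210 tests of lists along age, camera passed 93, 8 passed with an estimated correlation and 14 passed fry. Of 208 by genotype the counts were 50, 7 and 6. The E16 library was compared with postnatal libraries without a test, and a count of 0 was set to 3 counts for a lower bound of the ratio.

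The comparisons, tests, gene lists, markers and the rule for named genes were chosen before the data were examined. A further list of glucocorticoid targets was added after the data were seen. The rule took, in each tested comparison, the 6 largest positive and 6 largest negative changes with an adjusted p under 0.05 and a mean log2 CPM of at least 5, without receptor segments, Gm and Rik models, ribosomal pseudogenes and sex-linked genes. It added up to 4 members with the smallest p of each list named, and the interval genes by genotype. Where fewer than 12 genes passed, those that passed and the 6 of smallest p were taken. Without a test, it took the 8 largest ratios each way among genes with at least 50 CPM on the higher side, with separate intervals and outside the range of the postnatal libraries.

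The fits were tested on simulated counts with 200 genes changed by a known amount. For the age slope in NK-like cells (7998 genes) edgeR recovered 27.8% of genes changed by 0.5 log2 and 87% of those changed by 1, and 2.56% of its calls were false. For genotype in NK-like cells (5562 genes) it recovered 18.6% and 77.3%, with 5.10% false. For CD8 T-like cells it recovered 33.7% and 86% along age (9574 genes; 4.80% false) and 33.3% and 78% by genotype (7714 genes; 7.56% false).

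Alternatives were DESeq2, no filter on low counts, no TMM, a looser cell filter (200 genes, 500 UMIs, 20% mitochondrial), Leiden resolutions of 0.5 and 2.0, removal of scrublet doublets, at least 30 cells per pool, the largest-hashtag rule, age in weeks, E16 added to the slope, the pool as unit, no library covariate and each library left out. Alternatives chosen after the data were seen were the addition of cells without a hashtag, the larger CD8 cluster alone, shares of all cells, sex as a further covariate, shares of pools with at least 50 lymphoid cells and a spread taken from pools of all ages for the libraries of 2 weeks. Removal of scrublet doublets started from the cells of the largest-hashtag rule, so both rules changed in that alternative. The 3-week pools were not used for genotype. Sex entered 1 alternative as a covariate, where 110 gene-by-class differences passed for sex (72 outside Xist, Tsix and Y-linked genes). Apart from those of Ifitm1, these are not described further. Counts of genes that passed include results for single genes that are not reported here.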

Results

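Brain immune cells of wild-type (WT) mice and of mice carrying the 15q duplication (15q dup) were profiled by droplet RNA sequencing on embryonic day 16 (E16) and at 5 postnatal ages between 1 and 6 weeks. The sort kept CD45+ cells that were positive for CD90.2, NK1.1 or both. There were 8 WT and 7 15q dup mice at E16, 11 and 8 at 1 week, 10 and 13 at 2 weeks, 7 and 10 at 3 weeks, 9 and 9 at 4 weeks, and 7 and 7 at 6 weeks. The 2-week mice were spread over 3 libraries, here called A, B and C, and every other age was 1 library. Each listed hashtag marked a pool of mice of 1 genotype and 1 sex, so the pool or the library, not the cell, is the unit of every test. Genotype and sex were given for the pools of every age except 3 weeks, whose pools therefore enter no comparison of genotypes.

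Sequencing depth differed between libraries. Total gene UMIs were 23944633 at E16, 21405478 at 1 week, 39511247, 45974722 and 33029092 in libraries A, B and C of 2 weeks, 44482862 at 3 weeks, 37146777 at 4 weeks and 19123896 at 6 weeks. In the same order, 2133, 2637, 8175, 8084, 5570, 7402, 5909 and 3840 cells passed the filters, and 1414, 1992, 3293, 5660, 5203, 6397, 4249 and 2994 of them carried exactly 1 hashtag. The lymphoid cells among these numbered 173, 1511, 2188, 2896, 3592, 5935, 1644 and 2261, with a median of 11332, 6938, 4300, 5290, 5472, 4837, 5288 and 3798 UMIs per cell. E16 thus had the fewest lymphoid cells and the highest median of UMIs per lymphoid cell.

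The first question was which cells the sort had recovered. The 31202 cells with 1 hashtag formed 34 clusters, and most lymphoid clusters could be named from fixed markers. CD4 T-like cells (3593) expressed Cd3e in 97.5% and Cd4 in 58.4% of cells. CD8 T-like cells formed a large cluster of 3365 cells and a smaller one of 619 led by Gzmk, Ccl4, Ccl5, Ccl3 and Ly6c2. NK-like cells (1439) were led by Klra4, Gzma, Klra8, Klri2 and Ncr1, with Ncr1 in 95.3% and Cd3e in 4.38% of cells. Treg-like cells (1027) were led by Foxp3, Tnfrsf4 and Ctla4, gamma-delta T-like cells by Cd163l1, Tcrg-V6, Trdv4 and Blk, and ILC2-like cells by Rnf128, Stab2, Il1rl1 and Kit. ILC3-like cells (554) were led by Igfbp7, Lta, Hmgn3 and Upp1, NKT-like cells (501) by Klra1, Klra7, Klra6 and Cd160, and proliferating lymphoid cells by histone genes, Pclaf, Top2a and Cdc20.

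Further lymphoid clusters were left without a name because the marker scores of more than 1 cell type were close. The Zbtb16 cluster (1565 cells, Zbtb16, Trgv2, Zfp683, Cd40lg) had Cd3e in 93.4%, Zbtb16 in 33.4% and Klrb1c in 23.1% of cells. The Gzmc cluster (955 cells, Gzmc, Xcl1, Ccl1, Klrb1a, Klrb1b, Ncr1) had Ncr1 in 81.1% and Cd3e in 20.1%. The Dock2 cluster (536 cells, median 1912 UMIs) was tested for its share only, and the Ifit1 cluster (75 cells) was not tested. Despite the sort, border macrophage-like cells (Cbr2, Cd209f, Clec10a), microglia-like cells (Sparc, Tmem119, P2ry12), B-like cells, dendritic-like cells and 282 astrocyte-like cells (Ptprz1, Fabp7) were also present. Cells with several hashtags were left out as doublets, and a pair of clusters with C1qa and Cd3e together (746 and 352 cells) was set aside as a mixed T and macrophage profile.

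How the make-up of the lymphoid cells changed with age was asked over the 7 postnatal libraries. The Zbtb16 cluster expanded and ILC3-like cells contracted, and no other class passed its test. The Zbtb16 cluster rose from 3.11% of sorted lymphoid cells at 1 week to 4.02, 4.52 and 5.35% in the 3 libraries of 2 weeks, 7.67% at 3 weeks, 12.6% at 4 weeks and 19.6% at 6 weeks (Spearman rho 0.964, exact permutation p = 0.00238, Benjamini-Hochberg adjusted p = 0.0286, Pearson r 0.915, or 0.972 without the 2 farthest libraries). ILC3-like cells fell from 8.41% at 1 week to 1.28% at 4 weeks and 0.354% at 6 weeks (rho -0.927, exact permutation p = 0.00714, adjusted p = 0.0429, Pearson r -0.898, or -0.902 without the 2 farthest). As a share of all cells, ILC3-like cells passed and the Zbtb16 cluster did not (rho 0.852, adjusted p by exact permutation 0.143). With any 1 library left out, no class passed the exact Spearman test over 6 libraries, and by exact permutation of Pearson r both passed without library A or B of 2 weeks (adjusted p = 0.0333).

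**Figure D1:**
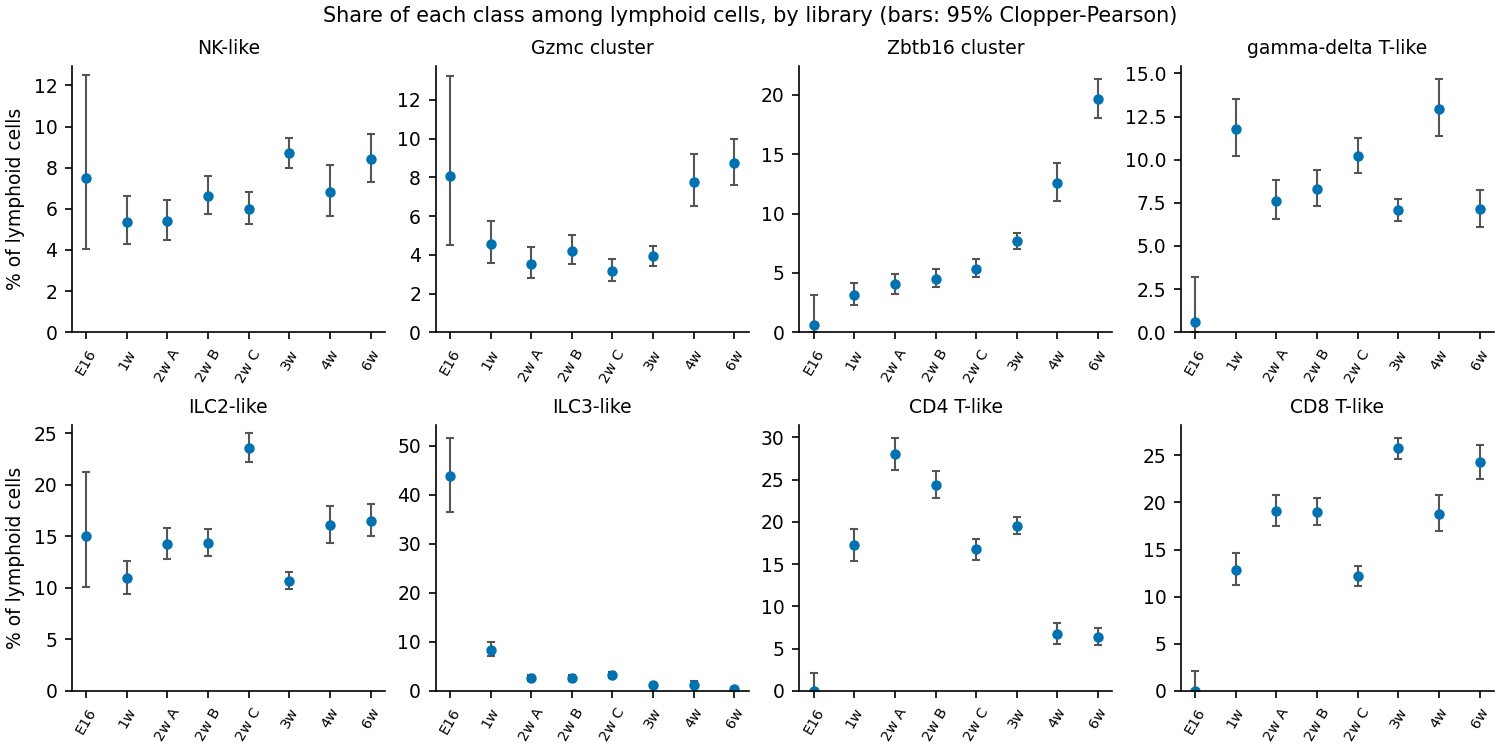
Share of lymphoid cells (y, percent, with 95% binomial intervals) in each library (x) for 8 classes. The Zbtb16 cluster is higher at each later age and ILC3-like cells are highest at E16.

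Values for the other classes did not pass in the main test. NK-like cells were 5.36% at 1 week and 8.40% at 6 weeks (rho 0.852, exact permutation p = 0.0238, adjusted p = 0.0952, Pearson r 0.769, or 0.555 without the 2 farthest), and passed only with cells without a hashtag added (rho 0.927, adjusted p by exact permutation 0.0262). CD4 T-like cells were 17.2% at 1 week and 6.37% at 6 weeks (rho -0.593, adjusted p by exact permutation 0.424), and proliferating cells were 16.4% and 1.55% (rho -0.445, adjusted p by exact permutation 0.493). Cells counted as NK by marker UMIs alone were 5.23% at 1 week and 12.1% at 6 weeks, and 8.26% and 12.2% after every cell was thinned to 1500 UMIs. At E16, ILC3-like cells made up 43.9% of lymphoid cells (76 of 173, 95% interval 36.4 to 51.7), proliferating cells 21.4%, ILC2-like cells 15.0% (10.1 to 21.2) and NK-like cells 7.51% (4.06 to 12.5). CD4 T-like, CD8 T-like and Treg-like cells were 0 of 173 each (95% interval up to 2.11%). These classes rest on clusters, and cells with T cell transcripts were present at E16. Cells with a Cd3e, Cd3d or Cd3g UMI and no Ncr1 or Klrb1c UMI made up 30.6% of its lymphoid cells. After thinning to 1500 UMIs they made up 26.6%.

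What changed inside each class as the postnatal brain matured was tested as a slope on log2 age. NK-like cells gained receptor and granule genes and lost cell cycle genes. ILC2-like cells lost type 2 cytokines, CD8 T-like cells gained effector genes as their smaller cluster made up more of them, and several classes gained Tsc22d3, Zfp36l2 and Camk2n1. Over 11 classes, 694 gene-by-class slopes rose and 651 fell, 1345 in all, at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. DESeq2 gave 1339, and 12486 of 93306 had an unadjusted p under 0.05. The total was 750 without the 1-week library, 812 without library B and 778 without library C of 2 weeks, 2639 without 3 weeks and 755 without 4 weeks. Slopes below are log2 per doubling of age ± SE, with the adjusted p of the same test and CPM at 1 and 6 weeks.

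In NK-like cells 111 genes rose and 167 fell among 8216 tested, with 1373 at an unadjusted p under 0.05 and 230 in DESeq2. Genes of the Ly49 receptor family were among those that rose: Klra4 (1.30 ± 0.20, adjusted p = 0.00073, 30.6 to 847 CPM), Klra8 (1.23 ± 0.13, 2.5e-05, 42.5 to 579), Klra1 (1.11 ± 0.16, 0.000411, 5.11 to 98.9) and Klra9 (0.97). Klra4 and Klra8 are also among the genes that set this cluster apart. The kinase inhibitor gene Camk2n1 (1.69 ± 0.15, 2.8e-06, 5.11 to 117), granzyme B (Gzmb, 1.18 ± 0.12, 2.4e-05) and the chemokine Ccl4 (1.18 ± 0.22, 0.00272, 17.0 to 334) rose with them. The cell cycle genes Rrm2 (-1.59 ± 0.22, 0.000222, 95.3 to 7.96), Pclaf (-1.49 ± 0.21), Mki67 (-1.24 ± 0.19, 0.000595, 71.5 to 4.55), Pola1 (-1.21 ± 0.19) and Tipin (-1.11 ± 0.15) fell, as did the linker histone H1f0 (-1.50 ± 0.20). The count was 69 without 1 week, 535 without 3 weeks, 154 without 4 weeks, 573 without 6 weeks and 51 with finer clusters (resolution 2.0).

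Fixed lists gave the same picture in NK-like cells. Of 17 proliferation genes, 15 fell (17 adjusted over the list alone), among them Hmgb2 (-0.81) and Mcm3 (-0.94), with a median slope of -0.99 (camera adjusted p = 2.4e-43). Of 22 Ly49 and NK receptor genes 11 rose and 1 fell (adjusted over the list alone, 14 and 3, camera adjusted p = 9.0e-15). Of 12 cytotoxic granule genes 5 rose (7 adjusted over the list alone, 1.6e-08), with Gzmc (2.05), Prf1 (0.78) and Fasl (0.65) beside Gzmb. Of 9 activation and checkpoint genes 3 rose, Tigit (1.08), Tnfrsf9 (0.84) and Tox (0.62), and Cd38 (0.62) did not pass. These 4 lists also passed with an estimated correlation, at 0.0382 for proliferation, cytotoxic granule and activation and 0.0499 for the receptors. NK maturation genes (5 of 13 rose, with Irf8 0.51 and S1pr5 0.83 beside Gzmb and Prf1, camera adjusted p = 3.5e-09) did not (adjusted p = 0.097 with an estimated correlation).

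**Figure D2:**
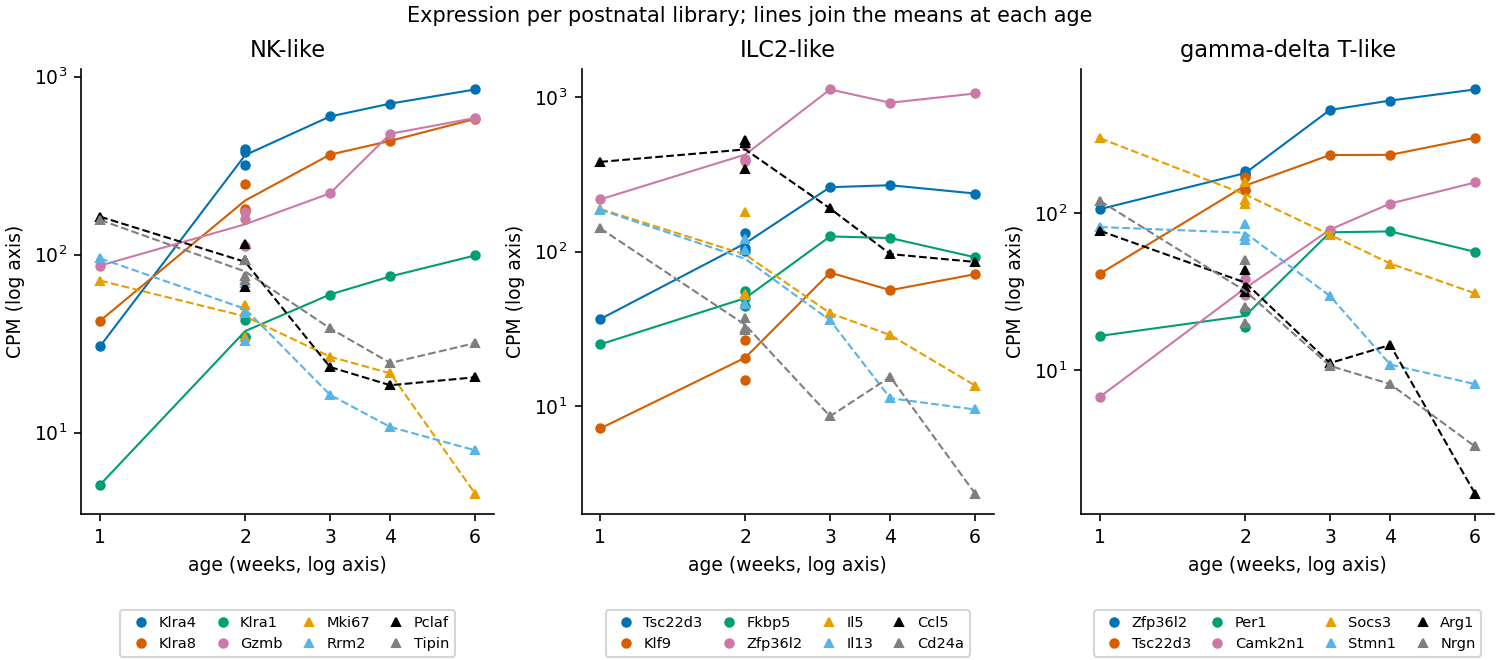
Expression (y, CPM, log axis) against age (x, weeks, log axis) of 8 genes each in NK-like, ILC2-like and gamma-delta T-like cells, with 1 point per postnatal library and lines through the mean at each age. Circles and solid lines mark genes that rose, triangles and dashed lines genes that fell.

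In CD8 T-like cells 191 genes rose and 70 fell among 9746 tested (1542 at an unadjusted p under 0.05, DESeq2 296). Effector molecules were among those that rose: Ccl4 (5.91 ± 1.19, adjusted p = 0.0196, 0 CPM at 1 week, 1072 at 4 weeks and 159 at 6 weeks), Xcl1 (3.65 ± 0.65, 0.0115, 1.55 to 155), Gzmk (2.61 ± 0.44, 0.00981) and the NKG2D receptor gene Klrk1 (1.56 ± 0.29). The T-box factor gene Tbx21 (1.54 ± 0.30) and Ly6a (1.64 ± 0.30, 57.5 to 540) rose as well. Ccr7, which guides naive T cells to lymph nodes, fell (-0.73 ± 0.12, 0.0103, 837 to 262), as did Arl5c (-0.61), Ccs (-0.60), Klhdc2 (-0.59), H2-Oa (-0.56) and Wdr12 (-0.56). Ccl4 and Gzmk define the smaller CD8 cluster, whose share of CD8 T-like cells was 6.19% at 1 week, 2.39 to 4.17% at 2 weeks, 6.48% at 3 weeks, 43.0% at 4 weeks and 59.1% at 6 weeks. Within the larger cluster alone, chosen for a test after this was seen, 18 genes rose and 28 fell. Of the genes named here only Ccs still passed there (-0.49, adjusted p = 0.0428). The slopes of Xcl1 (0.58, 0.486), Ly6a (0.35, 0.382), Klrk1 (0.71, 0.355), Tbx21 (0.58, 0.209) and Ccr7 (-0.22, 0.29) shrank and did not pass, and Ccl4 and Gzmk were not tested there, so the rise in effector genes goes largely with the mix of the clusters. The count of 261 was 163, 154 and 133 without libraries A, B and C of 2 weeks in turn, 646 without 3 weeks, 133 without 4 weeks, 26 without 6 weeks and 55 with coarser clusters (resolution 0.5).

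Several lists rose in CD8 T-like cells by camera, and none kept a pass with an estimated correlation. Interferon response genes rose in 8 of 17 cases (17 adjusted over the list alone, Rsad2 1.96, Usp18, Ifit3 1.49, Ifit1 1.31, camera adjusted p = 6.4e-24, adjusted p = 0.151 with an estimated correlation). Tissue residency genes rose in 7 of 15 (Itga1 2.73, Rgs1 1.85, Cxcr6 1.42 and Xcl1, 4.6e-14, adjusted p = 0.134 with an estimated correlation). Cytotoxic granule genes rose in 5 of 12 (Fasl 2.32, Prf1 1.07, Gzmm 0.76 and Gzmk, adjusted p = 0.176 with an estimated correlation) and effector cytokines in 4 of 9 (Ifng 3.09 beside Xcl1, Ccl4 and Ccl5, 0.174). Of 15 circulation and naive genes, Ccr7 and Klf3 (-0.48) fell and S1pr5 (2.68) rose, and S1pr1 (-0.45) did not pass (camera adjusted p = 1.2e-05, adjusted p = 0.306 with an estimated correlation).

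ILC2-like cells, innate cells that make type 2 cytokines, had 79 genes up and 84 down among 9562 tested (1646 at an unadjusted p under 0.05, DESeq2 226). Il13 (-1.82 ± 0.23, adjusted p = 0.00317, 187 to 9.53 CPM) and Il5 (-1.51 ± 0.27, 0.0126, 189 to 13.6) fell together with Cd24a (-2.11 ± 0.19, 0.000157, 142 to 2.72), Ccl5 (-1.17 ± 0.24), Hmgn2 (-0.91 ± 0.16) and H1f0 (-0.90 ± 0.18). Klf9 (1.29 ± 0.19, 0.00574), Camk2n1 (1.26 ± 0.20), Tsc22d3 (1.08 ± 0.15, 0.00505), Zfp36l2 (0.98 ± 0.13, 218 to 1055), Fkbp5 (0.88 ± 0.16) and Slain1 rose. Klf9, Tsc22d3 and Fkbp5 are known targets of glucocorticoid. Fetal and early lineage genes fell as a list (Cd24a, with Igf2bp3 -1.37 and Arid3a -0.66 not passing alone, camera adjusted p = 2.6e-09, and 0.0488 with an estimated correlation). Proliferation genes fell in 4 of 16 cases (Ube2c -1.94, Ccnb2 -1.82, Birc5 -1.80, Cenpa -1.22, 2.2e-12, adjusted p = 0.256 with an estimated correlation). The count of 163 was 26 without 1 week, 90, 91 and 99 without libraries A, B and C of 2 weeks in turn, 262 without 3 weeks, 60 without 4 weeks, 596 without 6 weeks and 10 with the slope on weeks.

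In gamma-delta T-like cells 73 genes rose and 119 fell among 9234 (1594 at an unadjusted p under 0.05, DESeq2 174). Camk2n1 (1.61 ± 0.13, adjusted p = 3.2e-06, 6.75 to 157 CPM), Zfp36l2 (1.11 ± 0.10, 1.7e-05), the clock gene Per1 (16.5 to 56.8), Tsc22d3 (0.93 ± 0.13, 0.00111), Krt83 and Pgm2l1 (0.78) rose. The cytokine signaling inhibitor gene Socs3 (-1.36 ± 0.10, 2.9e-06, 301 to 30.8), Nrgn (-2.10 ± 0.20, 2.0e-05), Serpine2 (121 to 4.87), Arg1 (-1.59 ± 0.20), Stmn1 (-1.32 ± 0.24) and Bcl3 (-1.31 ± 0.20) fell. Proliferation genes fell in 8 of 19 cases (16 adjusted over the list alone, Cenpa -0.87, Mki67 -0.89, Birc5 -1.23 and Stmn1, camera adjusted p = 3.9e-25, and 0.0268 with an estimated correlation). The count of 192 was 43 without 1 week, 97 and 120 without libraries B and C of 2 weeks in turn, 295 without 3 weeks and 44 without 4 weeks.

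ILC3-like cells could be followed from 1 to 4 weeks in 6 libraries, and 51 genes rose and 57 fell among 6887 (1022 at an unadjusted p under 0.05, DESeq2 36). Cd74 (3.91 ± 0.53, adjusted p = 0.000138, 1.88 CPM at 1 week, 62.6, 13.8 and 23.5 in libraries A, B and C of 2 weeks, 10.9 at 3 weeks and 560 in the 21 cells of 4 weeks, and a slope of 1.46, adjusted p = 0.238, without 4 weeks), Tsc22d3 (1.75 ± 0.18, 1.9e-06), Padi2, Nt5e (1.48), Vav3 (1.40) and Zfp36l2 (1.32) rose. Cks1b (-1.60), Apoe (-1.58), Mcm5 (-1.34), Dgat1 (-1.31), Stmn1 and Col18a1 (-1.29) fell, though Stmn1 turned to 0.40 without 1 week and Apoe to 0.25 with cells without a hashtag, and 9 of 10 proliferation genes fell (Mcm3 -1.04, Hmgb2 -0.94, Cenpa -1.12 and Mcm5, camera adjusted p = 1.2e-14, adjusted p = 0.298 with an estimated correlation). The count of 108 was 10 without 1 week, 58 without library B of 2 weeks, 53 without 3 weeks and 221 without 4 weeks.

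In the unnamed clusters genes moved both ways. In the Zbtb16 cluster 116 genes rose and 83 fell among 8961 (1358 at an unadjusted p under 0.05, DESeq2 193). The killing ligand gene Fasl (adjusted p = 0.000788, 39.1 to 162 CPM) and the interleukin 12 receptor gene Il12rb2 (1.13 ± 0.15, 0.000788) rose with Mdfic, Pmepa1 (1.17), H2-Q7 (1.14) and Gimap7 (1.05), while Rln3 (-1.59), Igfbp4 (226 to 10.8 CPM), Lmna (-1.40), Igf2bp3 (-1.23), Timp2 (-1.16) and Cxxc5 (-1.03) fell. The count of 199 was 314 without 1 week, 92, 95 and 61 without libraries A, B and C of 2 weeks in turn, 456 without 3 weeks, 69 without 4 weeks and 30 without 6 weeks. In the Gzmc cluster 32 rose and 27 fell among 7745 (752 at an unadjusted p under 0.05, DESeq2 43). The inhibitory receptor gene Tigit (1.25 ± 0.19, 0.000766), Jaml (1.08), Fkbp5 (0.92), Styk1 (0.92), Tsc22d1 (0.86) and Klrc2 rose, and Ifitm1 (-2.75 ± 0.40, 0.000577, 812 to 33.1 CPM), Ifitm2 (-1.43), Ifitm3 (-1.28), H1f0 (-1.49), Arg1 (-1.36) and Klf2 (-1.32) fell. Without 1 week Ifitm1 turned to 0.92 and Ifitm3 to 0.60 and Ifitm2 was -0.30, so these falls rest on that library. Its activation (2 of 11 rose, Tigit and Lag3 1.28, Entpd1 0.52 and Cd38 0.44 did not pass) and tissue residency genes (1 of 11, Litaf 0.72, Xcl1 0.58, Cxcr6 0.34 and Itga1 0.36 did not pass) both passed camera with an estimated correlation, at 0.0357. The Gzmc count of 59 was 13 without 1 week, 148 without 3 weeks and 34 without 4 weeks.

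The remaining classes moved less. Treg-like cells had 29 genes up and 21 down among 7849 (941 at an unadjusted p under 0.05, DESeq2 37): the checkpoint gene Pdcd1 (1.51 ± 0.22, adjusted p = 0.00216), Cd74 (1.13), Socs1 (1.06), Gbp6 (1.05), Neb (0.92) and Ddit4 (0.90) rose, and Hist1h1b, Tk1 (-1.07), Hist1h3e (-0.99), Rgcc, Rras2 (-0.78) and Mcm5 (-0.77) fell. CD4 T-like cells had 6 up, Fgf13 (1.72), Ddit4 (1.03), H2-Q7 (0.97), AW112010 (0.90), Dnaja1 (0.62) and Ly6e (0.51), and 9 down, led by Myo6 (-1.50 ± 0.13, 9.7e-06, 199 to 16.5 CPM), Hist1h3e (-1.50), Tubb2b (-1.44), Hist1h1e (-1.34), Ecm1 (-0.86) and Gimap5 (-0.59), among 9523 (946 unadjusted, DESeq2 43). NKT-like cells had 1 up (H2-Q7) and 9 down among 5523 (398 unadjusted, DESeq2 11), led by Gzma (-2.01), Klra5 (-1.60), Gzmb (0.0746 without scrublet doublets), Hist1h1d (-1.44), Ccnb2 (-1.26) and Cenpa (-1.13). Proliferating lymphoid cells, among 10060 (914 unadjusted, DESeq2 50), had 5 up (Fgf13, H2-Q7, Ly6a and Rsrp1 among them) and 5 down (Ifitm1 -3.51, Slc6a13 -2.32, Csf2 -2.13, Serpinb1a -1.21, Hist1h4d -0.57).

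Counts in these small sets also leaned on single libraries. For Treg-like cells the count of 50 was 11 without 1 week, 27 without library B or C of 2 weeks, 18 without 4 weeks, 247 without 6 weeks, 17 with the slope on weeks and 0 at resolution 0.5. For CD4 T-like cells the count of 15 was 2 without 1 week, 9 without library B or C of 2 weeks, 127 without 3 weeks, 9 without 4 weeks and 35 without 6 weeks. NKT-like cells had 10 genes, against 1 without 1 week, 23 without 3 weeks and 29 without 6 weeks. Proliferating cells had 10, against 2 without 1 week, 4 without library A and 2 without library C of 2 weeks, 19 without 3 weeks, 4 without 4 weeks and 3 without 6 weeks.

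How libraries of 1 age differ was asked beside the contrasts of neighboring ages, with pools as units. Pools of 1 library share its preparation, so these p-values are too small. Over all classes, 3484 gene-by-class differences passed between 2 weeks and 1 week, 17432 between 3 and 2 weeks, 7169 between 4 and 3 weeks and 689 between 6 and 4 weeks (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Between the libraries of 2 weeks, 13, 124 and 78 passed with the spread of pools of all ages. A joint test of these 3 libraries passed for 153 with that spread and for 1103 with the spread of the 2-week pools alone, which comes from the 2 pools of library C. Library A held WT male, B 15q dup male and C female pools, so these contrasts also hold genotype and sex. The 3-week library stood apart by gene length: its deviation from the 2-week and 4-week libraries had a median Spearman correlation of 0.538 with gene span over the classes, against -0.165 for 1 week and 0.0682 for 4 weeks.

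**Figure D3:**
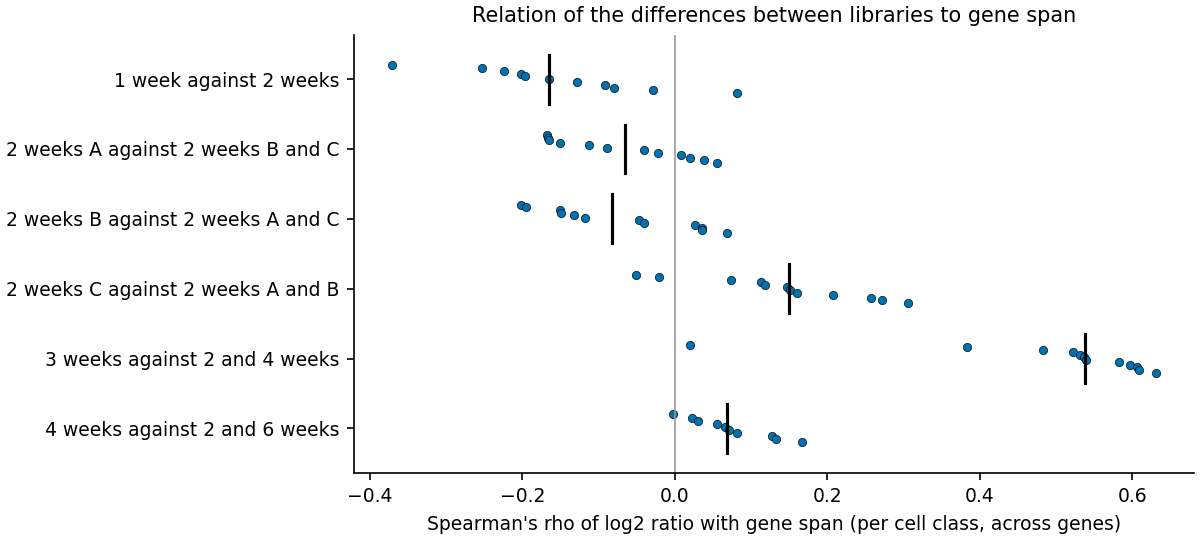
Spearman correlation (x) between gene span and the log2 ratio of libraries, with 1 point per cell class and the median as a bar, for each contrast of libraries (y). Most points of the 3-week library lie to the right of those of the other contrasts.

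The embryonic library was set against the postnatal libraries in the 4 classes with enough E16 cells. Among proliferation genes with at least 50 CPM at E16 or postnatally, most were higher at E16 in ILC3-like and ILC2-like cells. These were 11 and 7 of the 20 listed. In proliferating cells all 20 reached that level, and there 1 was higher and 10 were lower at E16. List counts below likewise cover only members with at least 50 CPM at E16 or postnatally. With 1 library at E16 there is no test, and intervals cover counting error only. Genes outside the range of the postnatal libraries with separate intervals numbered 564 higher and 502 lower in ILC3-like cells (76 cells against 470, 449 and 561 with TMM scaling), 763 and 371 in ILC2-like cells (26 against 3011, 382 and 663 with TMM scaling), 425 and 495 in proliferating cells (37 against 1150, 365 and 542) and 700 and 763 in border macrophage-like cells (786 against 4586, 1057 and 488). In ILC2-like cells the median of genes with at least 50 CPM on the higher side and counts on both sides lay 0.21 log2 above 0 at E16. The counts with and without TMM scaling show that the split of higher and lower genes there turns on the scaling. Genes beyond the postnatal range by both scalings were 440 higher and 480 lower, 382 and 371, 362 and 490, and 700 and 486.

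In ILC3-like cells the imprinted genes H19 (126 CPM, 95% interval 104 to 152, against 2.20, 57.2-fold) and Dlk1 (375, 336 to 417, against 11.6, 32.2-fold) were higher at E16, as were Ifitm1 (17.1-fold, carried by the WT pools, with 15q dup 6.82 log2 lower at E16), Tpm2 (15.0-fold), Krt18 (14.5-fold) and Arid3a (9.68-fold). The gut-homing receptor gene Ccr9 (3 postnatal counts) was 62.6-fold higher (20.3 to 313) and Hist1h2bc (2 counts) 81.5-fold (21.3 to 693). Lower genes were Upp1 (0 counts against 286 CPM, at least 85.4-fold), Gimap3 (against 688 CPM), Anxa1 (35.8-fold), Klrb1f (26.0-fold) and Bhlhe40 (24.5-fold), and with 1 to 3 counts at E16 Hk3 (47.4-fold, 8.39 to 1883), Ly6a (33.3-fold, 11.3 to 162) and the NK receptor gene Ncr1 (29.2-fold, 9.92 to 143). Upp1 is among the genes that define this cluster. Of 11 proliferation genes 10 were higher (median log2 ratio 1.23), 4 of 4 fetal genes were higher (4.14) and 4 of 5 interferon genes were lower (-1.46). In this class the T cell marker Cd163l1 was 8.47 log2 lower in 15q dup at E16. A different mix of cells at E16 is thus not excluded for these differences.

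ILC2-like cells at E16 were higher in the guidance gene Slit2 (234 CPM, 180 to 300, 155-fold), Akap6 (223-fold), the Notch target Hey1 (217-fold), Nrp2 (181-fold), Gulp1 (117-fold), Slc22a3 (87.0-fold), Meis1 (25.5-fold) and Slc38a4 (383-fold). Most E16 cells of this class came from the WT pools, where they were 16.3 and 23.9% of 43 and 67 lymphoid cells. In the 15q dup pools they were 9.09 and 0% of 33 and 30. The postnatal side holds both genotypes, so age is not separated from genotype in this class. Ccl5 had 0 counts at E16 against 318 CPM (at least 28.5-fold) and H2-Q7 0 against 212 CPM. The CGRP receptor component gene Ramp1 (132-fold lower, 23.6 to 5195), Bhlhe40 (43.1-fold, 7.74 to 1704), Dach2 (34.0-fold, 6.09 to 1343) and Padi2 (22.4-fold, 4.01 to 885) had 1 count each at E16, H2-Q4 had 2 (18.0-fold, 4.97 to 149) and Nrgn was 17.4-fold lower. Of 7 proliferation genes 6 were higher (median 1.70), and 4 of 6 effector cytokine genes were lower (-0.89).

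Proliferating cells at E16 were higher in Ifitm1 (1129 CPM, 1048 to 1215, against 34.3, 32.9-fold), Mdk (28.3-fold), Dlk1 (24.8-fold), Ifitm2 (23.9-fold), Htra3, Ifitm3 (15.0-fold) and Klra5 (13.1-fold). Pf4 (12.9-fold, 138 CPM) was 7936 CPM in the border macrophage-like cells of E16, so RNA from those cells is not excluded for it. Lower genes were Cd8b1 (at least 67.2-fold), Cd5 (against 165 CPM), Slamf6 (at least 25.4-fold) and the arginine synthesis gene Ass1 (at least 61.9-fold), with 0 counts, and Trac (79.5-fold lower, 14.2 to 3142), Ctla4 (57.4-fold, 10.3 to 2269) and Cd8a (33.6-fold, 11.5 to 163), with 1 to 3. Ifi27l2a was 7.86 against 793 CPM. This class holds dividing cells of any lymphoid lineage, and CD4 T-like, CD8 T-like and Treg-like cells were 0 of 173 lymphoid cells at E16. Of 12 Ly49 and NK receptor genes in it, 9 were higher and 1 was lower at E16. The lower values of T cell genes such as Cd8b1, Cd8a and Trac are thus not separated from a different mix of lineages. Border macrophage-like cells at E16, mostly of 1 cluster led by Pf4 and Fcna (745 of 786), were higher in H19 (232-fold), Cdkn1a (10.9-fold), Lmna (10.4-fold) and Tmc8 (8.58-fold), and held more red cell RNA, Hbb-bt (37.2-fold), Hba-a2 (23.7-fold), Hba-a1 (488 CPM) and Hbb-bs (919 CPM), not read as expression of these cells. They were lower in Cbr2 (15.5 against 1310 CPM), the complement gene C4b (74.2-fold), Ccl8 (67.5-fold), Cd209g (0.841 against 55.5 CPM), Cd209f (21.2-fold), Ddit4 (10.6-fold), Klf4 (10.1-fold) and Wfdc17 (9.39-fold).

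Whether the duplicated genes were expressed in excess was asked first, on counts summed over all lymphoid cells of 9 WT and 8 15q dup pools, with both genotypes in 4 libraries. They were: the ubiquitin ligase genes Ube3a and Herc2 were higher in 15q dup, and no other gene passed. Ube3a (chromosome 7, 59228750 to 59311536) was 0.48 ± 0.06 log2 higher (adjusted p = 0.00463, 93.8 ± 5.86 CPM in WT and 132 ± 16.0 in 15q dup, mean ± SD), and Herc2 (56050196 to 56231800) 0.50 ± 0.07 (0.00748, 55.6 ± 9.42 and 82.4 ± 4.10). Each was higher in 4 of 4 libraries. Of 11965 genes tested 2 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, both higher, and 664 had an unadjusted p under 0.05.

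Among the 13 interval genes 5 could be tested and all 5 were positive. The WT means include 1 E16 pool with no 15q dup pool of that age beside it, where Ndn was 7.31 CPM. Ndn (1.48 CPM in WT and 4.00 in 15q dup, adjusted p = 0.153), Snrpn (0.58 ± 0.26, 0.865) and Atp10a (0.17 ± 0.09, 0.922) did not pass, and over the interval genes alone the adjusted p was 1.9e-06 for Ube3a, 3.1e-06 for Herc2, 0.000107 for Ndn, 0.0437 for Snrpn and 0.0646 for Atp10a. Of the neighboring genes, Nipa1 (2.02 ± 0.34, adjusted p = 0.0523, 1.27 and 5.11 CPM), Nipa2 (-0.18, lower in 15q dup in 4 of 4 libraries), Cyfip1 (0.19) and Tubgcp5 (0.07) did not pass, and over these neighbors alone the adjusted p was 5.25e-05 for Nipa1, 0.0327 for Nipa2, 0.293 for Cyfip1 and 0.549 for Tubgcp5. Outside the region the smallest p-values belonged to Fos (1.87 ± 0.35, not passing) and Csf2 (0.79 ± 0.16, adjusted p = 0.169). In T-like cells alone both genes passed (Herc2 0.56 ± 0.09, adjusted p = 0.0238, Ube3a 0.40 ± 0.08, 0.0296) among 30 genes higher and 2 lower of 9804, so there most genes that passed lie outside the interval, and in NK-like cells alone neither did (Ube3a 79.9 and 131 CPM, adjusted p = 0.389, Herc2 0.54 ± 0.20, adjusted p = 0.999, or 0.00137 and 0.0144 over the interval genes alone). The difference between T-like and NK-like cells was not tested.

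**Figure D4:**
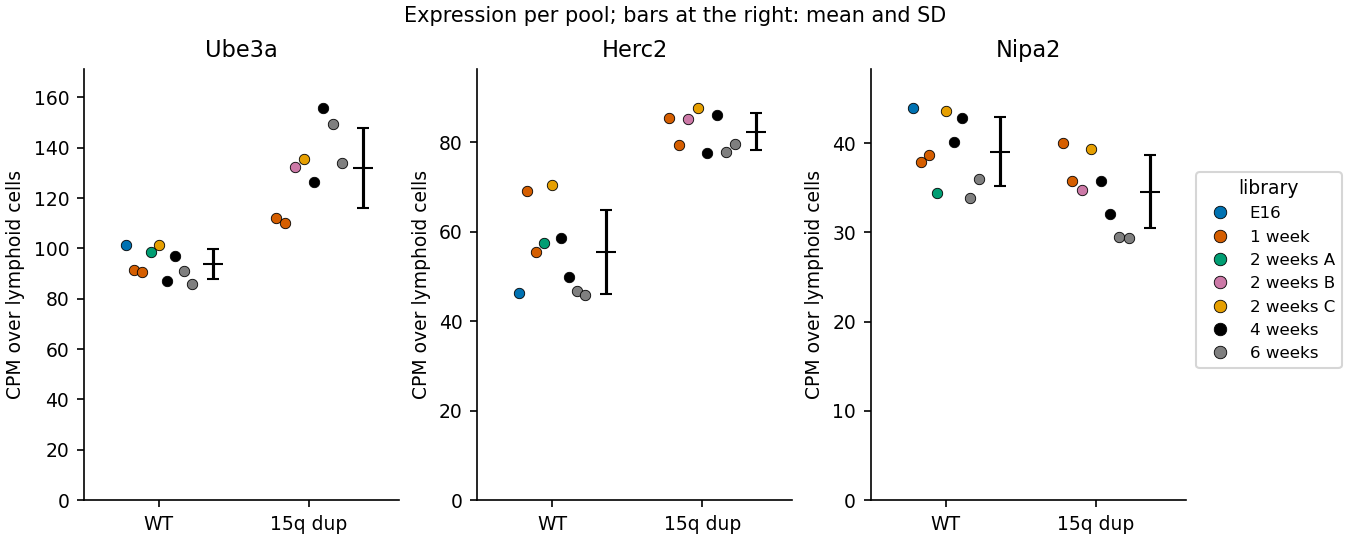
CPM (y) of Ube3a, Herc2 and the neighboring gene Nipa2 in sums over all lymphoid cells, with 1 point per pool colored by library, by genotype (x), and mean and SD beside them. Ube3a and Herc2 are higher in the 15q dup pools, and Nipa2 is not.

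What the duplication changed within each class was tested with the library as a covariate. Few genes passed, and no class had more than 7. Over 11 classes 15 gene-by-class differences were higher and 9 lower in 15q dup, 24 in all, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. DESeq2 gave 2, and 2872 of 71996 had an unadjusted p under 0.05. Exchanging genotype labels within libraries gave at least 24 in 11 of 40 splits, the real one included, so chance is not excluded for this count. Log2 ratios of 15q dup over WT ± SE follow.

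ILC2-like cells of 15q dup mice had 6 genes higher and 1 lower (326 unadjusted, DESeq2 0). The higher ones were the growth factor gene Csf2 (0.93 ± 0.20, adjusted p = 0.0367, 64.8 and 139 CPM, higher in 3 of 4 libraries), the CGRP gene Calca (1.83 ± 0.36, 0.0234, 41.9 and 160, 3 of 4), Ccl1 (2.04 ± 0.30, 0.000271, 2 of 4), the immediate early genes Fos (2.79 ± 0.42, 0.000271, 3 of 4) and Egr3 (2.28 ± 0.44, 0.0224, 4 of 4), and Plac8 (1.27 ± 0.27, 0.0367, 4 of 4, with about equal mean CPM). Immediate early and dissociation genes were up as a list by camera (1 of 14 passed, Zfp36 0.52, Egr1 0.97 and Junb 0.27 did not, 5.1e-06, adjusted p = 0.0608 with an estimated correlation). Effector cytokines were up by camera too (Csf2, with Il13 0.89, Tnf 0.79 and Lta 0.37 not passing, adjusted p = 0.0608 with an estimated correlation). A response to tissue dissociation that differs between pools was not separated from an effect of genotype. The 15q dup pools differed widely: Calca was 160 ± 274 CPM, Ccl1 82.8 ± 132, Csf2 139 ± 111 and Fos 29.3 ± 31.1 (mean ± SD). The count of 7 was 4 without library C of 2 weeks and 3 without 4 weeks.

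NK-like cells had 3 genes higher and 0 lower (226 unadjusted, DESeq2 0): Cox6a2 (2.45 ± 0.37, adjusted p = 0.000102, 15.9 and 40.3 CPM, 4 of 4 libraries), the chemokine Ccl4 (1.37 ± 0.29, 0.0369, 81.6 and 238, 3 of 4) and Nr4a1 (2.92 ± 0.48, 0.000458, 8.48 and 53.5, 3 of 4). Nr4a1 is on the immediate early and dissociation list, so a dissociation response that differs between pools is not excluded for it. NK maturation genes were down by camera (0 of 11 passed, Zeb2 -1.06, Cma1 -1.04, Gzmb -0.58 and S1pr5 -0.50, 6.1e-08, adjusted p = 0.133 with an estimated correlation). The 15q dup pools differed widely here too: Nr4a1 was 53.5 ± 83.5 CPM, Ccl4 238 ± 249 and Cox6a2 40.3 ± 48.0 (mean ± SD). The count of 3 was 1 without library C of 2 weeks and 1 without 6 weeks. In the Gzmc cluster Ube3a (0.94 ± 0.19, adjusted p = 0.0211, 84.6 and 148 CPM) and the interleukin 7 receptor gene Il7r (0.87 ± 0.16, 0.0108, 127 and 228) were higher in 4 of 4 libraries, the integrin gene Itga4 was lower (-1.06 ± 0.22, 0.0275), and Il13 was found in 15q dup pools of 1 library only. Its count of 5 (234 unadjusted, DESeq2 0) was 1 without 4 weeks.

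In CD4 T-like cells interferon response genes were lower in 15q dup as a list (13 tested, among them Ifi27l2a -0.36, Ifi47 -0.30 and Ifi213 -0.40, which did not pass singly over all genes, camera adjusted p = 6.9e-09, and 0.0162 with an estimated correlation), with 155 genes there at an unadjusted p under 0.05 and DESeq2 0. CD8 T-like cells had only Hbb-bs (6.26 ± 0.45, adjusted p = 1.3e-06, 1 of 4 libraries) and Hba-a2, red cell RNA (260 unadjusted, DESeq2 0, 0 without library C of 2 weeks, 5 without 6 weeks). ILC3-like cells had Gzma higher (4.42, 2 of 3 libraries) and Cd163l1 (-3.32), Ifitm1 (-4.82) and Cd3e (-4.59) lower, of which Cd163l1 and Cd3e are T cell markers, so cells of another type are not excluded (353 unadjusted, DESeq2 0), and the 4 were 2 without E16, where Ifitm1 turned to 0.16, and 2 without 1 week. NKT-like cells had only receptor segments, Trbv12-2 and Trbv15 (90 unadjusted, DESeq2 1), and the 2 were 1 without library C of 2 weeks and 5 without 4 weeks.

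In gamma-delta T-like cells 0 genes passed edgeR (322 unadjusted, DESeq2 0), and 0 passed in proliferating (375, DESeq2 0), Treg-like (148, DESeq2 0) and Zbtb16 cluster cells (383, DESeq2 1). In gamma-delta T-like cells 3 passed without 1 week, 3 without 4 weeks and 1 without library C. In Treg-like cells 1 passed without 1 week, library C or 6 weeks, and in the Zbtb16 cluster 4 passed without library C, 3 without 4 weeks and 1 without 6 weeks. The interval genes were up as a list with an estimated correlation in CD4 T-like cells (median 0.43, adjusted p = 0.0162), gamma-delta T-like cells (0.54), ILC3-like cells (0.71, 0.0277) and the Zbtb16 cluster (0.55, 0.0405). Tissue residency genes were up in gamma-delta T-like cells (0 of 8 passed, Ahr 0.43, Bhlhe40 0.36, Cxcr6 0.15, Rgs1 0.36, camera adjusted p = 0.00194, and 0.0442 with an estimated correlation) and Ly49 and NK receptor genes in the Zbtb16 cluster (0 of 13 passed, Klra5 1.43, Klrb1c 0.47, Klrb1b 0.64, Klra7, 3.0e-06, and 0.0405 with an estimated correlation). Proliferation genes were down in gamma-delta T-like cells by camera only (0 of 17 passed, Pclaf -1.59, Ube2c, Rrm2 -1.63, Top2a, adjusted p = 0.525 with an estimated correlation).

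Genotype was also compared at single ages, where a library held 2 pools of each genotype. This leaves out every contrast at 2 weeks and those at 1 week in NK-like cells and the Gzmc and Zbtb16 clusters. In the remaining contrasts 53 differences passed and 7 in DESeq2. ILC2-like cells at 1 week had higher Calca (3.03 ± 0.45, adjusted p = 0.000562) and Csf2 (1.64 ± 0.29, 0.00757). NK-like cells had higher Nr4a1 (3.70 ± 0.59, 7.1e-05) and lower Gzmb (-1.28 ± 0.26, 0.0108) at 6 weeks, and higher Lgals3 (1.92) and lower Camk1d (-1.13) at 4 weeks. A test of genotype by age, which includes the ages with fewer pools, passed for 28 genes (2281 unadjusted): 14 in NK-like cells, 6 in CD4 T-like cells, 5 in the Gzmc cluster, 2 in ILC2-like cells and 1 in proliferating cells. In NK-like cells Camk1d was 0.30, 0.45, -1.13 and 0.06 at 1, 2, 4 and 6 weeks and Cd3g -0.28, 0.32, -0.02 and -1.85. In CD4 T-like cells Hsp90aa1 was -0.05, 0.10, -2.41 and 0.23 and Junb 1.21, -0.20, -0.34 and -0.67, and the other 4 genes there were T cell receptor segments.

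Whether genotype changed the make-up of the sorted lymphoid cells was tested on shares of 9 WT and 9 15q dup pools in 5 libraries. No class passed. Gamma-delta T-like cells came closest, at 6.34 ± 4.33% in WT and 10.5 ± 6.24% in 15q dup (mean ± SD), higher in 15q dup in 5 of 5 libraries, of which E16 rests on 1 cell (exact permutation within libraries, p = 0.00463, Benjamini-Hochberg adjusted p = 0.278). ILC3-like cells were 13.9 ± 21.1% and 10.1 ± 14.4% (exact permutation p = 0.0386, adjusted p = 0.714).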

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

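The tests of gene length, depth per cell and dissociation were chosen only after the results they address had been seen, as was the rule that keeps single-genotype pools of 2 weeks in the splits by genotype. The list of glucocorticoid targets was also added after the data were seen.

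Of 18 groups of 8 or 9 pools examined for a pool far from the others, 3 had one, and chance gives about 1 in 20. All 3 were the E16 WT female pool, the smallest in the sums over lymphoid cells (67 cells), and all were neighbors of the interval: Tubgcp5 at 32.9 CPM, Cyfip1 at 42.7 CPM and Nipa1 at 3.66 CPM. The groups share this pool, so the 3 are not independent.

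The effect of genotype differed between ages by the joint interaction test for 14 genes in NK-like cells, 6 in CD4 T-like cells, 5 in the Gzmc cluster, 2 in ILC2-like cells and 1 in proliferating cells. Those in NK-like cells included Camk1d, Lgals3, Ifi27l2a, Cdk8, Cd3g, Nrgn, Il31ra, Tnfrsf9, Gphn, Nop58, Lars2, Cmss1 and Gm42418. In ILC2-like cells Ccl1 was -5.36 at 1 week, 2.95 at 2 weeks, 0.53 at 4 weeks and -0.21 at 6 weeks (log2, 15q dup over WT), and Cd74 was -0.62, 0.66, -1.37 and -2.01. In the Gzmc cluster Gzma was -1.87, 2.53, 1.93 and -1.57 and Stmn1 0.42, 0.66, -3.12 and 1.30. With 2 pools per genotype and age, and 1 in some, these values rest on few pools.

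Cells without a hashtag hold a large set of lymphoid cells in a pair of libraries that the comparisons leave out: 2700 in library A of 2 weeks and 1898 in library B, 55.3% and 78.3% of the cells without a hashtag there. By class they resembled the tagged cells, with 23.8 and 26.7% CD4 T-like, 23.3 and 21.9% CD8 T-like, 14.9 and 14.2% ILC2-like and 5.85 and 4.95% NK-like. Their pool is not recorded, so they enter no comparison of genotypes.

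The first pattern weighed is the 3-week library, which differs from each neighbor in more genes than the other adjacent ages do. Depth per cell is argued against as the cause, since 4837 UMIs per lymphoid cell at 3 weeks lie inside the range of the other postnatal libraries. Gene length is in line with a technical source, since the median Spearman correlation of the deviation with gene span was 0.538, above the contrasts among the libraries of 2 weeks (-0.0649, -0.0828 and 0.149). A difference in preparation is a possible source, and which step it would be was not tested. The biology of 3 weeks of age stays open and untested, because this age is 1 library.

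The second pattern is the number of genes that passed, set against other groupings of the same units. Exchanging genotype labels within libraries gave at least the 24 differences over the classes in 11 of 40 splits (highest other 35), and at least the 2 genes in the lymphoid sums in 3 of 40 (highest other 12), so chance is not excluded for either count. For interval genes that passed as higher, the real labels gave 2 and no other split gave any (1 of 40, highest other 0), so chance is excluded there. Exchanging ages between postnatal libraries gave at least the 1345 slopes in 2 of 40 assignments (highest other 1594), so chance is not excluded for the count of slopes. The assignment with 1594 ran partly against the real ages (correlation of log2 ages -0.68), and the count ignores the direction of a slope. That assignment is therefore not free of the real order, and the next highest gave 202. For adjacent ages with pools as units chance is excluded (28774 real, highest other 2192, 1 of 30 splits), but the real grouping is also the grouping by library, and library and age cannot be told apart.

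The third pattern is the rise of Tsc22d3, Fkbp5, Per1, Klf9, Ddit4 and Zfp36l2, targets of glucocorticoid, with age. These 6 genes were gathered after slopes along age had been seen, so their counts describe the pattern and do not test it. Of those tested, 5 of 6 rose in ILC2-like cells, 4 of 5 in ILC3-like cells and 6 of 6 in gamma-delta T-like cells. A shared response to glucocorticoid could explain this, but other targets not looked at along age before, of which 13, 7 and 14 were tested in these classes, did not rise as a list (lowest camera adjusted p over the 3 classes 0.218; medians -0.16, -0.05 and 0.09). A dissociation response was not borne out either (lowest adjusted p 0.0618, with a median of -0.07 in ILC2-like and ILC3-like cells). The cause of the rise in these genes stays open.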

How the results depend on the processing

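Sex as a covariate, cells without a hashtag, shares of all cells and the spread from pools of all ages were tests chosen only after the results had been seen. Over all results and alternatives, 3734 values stayed the same, 482 kept direction and no longer passed, 90 newly passed, 188 counts or values moved and 6 reversed. Same means the same side of the threshold, or for a count a change of at most 1.5-fold. It includes changes of sign where neither value passed. For example, the share of CD8 T-like cells had rho 0.556 with age in the main setting and -0.445 at resolution 0.5.

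The count of slopes along age (1345) was 1339 with DESeq2, 1405 with the looser cell filter, 1119 and 1036 at resolutions 0.5 and 2.0, 1284 without scrublet doublets, 900 on weeks and 1293 with cells without a hashtag. It was 2653 with no filter on low counts, 851 without TMM, 6387 with the pool as unit, 574 with E16 added (281 in the same classes without it), and 750 to 2639 with 1 library left out. Single classes moved more: ILC2-like cells had 10 on weeks (163), Treg-like cells 0 (50) and CD8 T-like cells 55 (261) at resolution 0.5, NK-like cells 51 (278) at 2.0, gamma-delta T-like cells 71 (192) on weeks, ILC3-like cells 36 (108) with DESeq2, the Gzmc cluster 21 (59) on weeks and the Zbtb16 cluster 96 (199) without TMM. Of the 1345, DESeq2 also called 1043, and 452 were left without 1 week and 1257 without 3 weeks. The cause of these moves was not tested, except that the pool as unit counts pools of 1 library as independent. The setting without scrublet doublets also took the largest-hashtag rule, so its counts do not show doublet removal alone. The genotype count (24) was 22 without TMM, 31 with the looser filter, 19 and 26 at the 2 resolutions, 25 without scrublet doublets, 26 with at least 30 cells per pool, 27 by the largest-hashtag rule and 22 to 30 with 1 library left out. It was 2 with DESeq2, 225 with no filter on low counts and 55 with sex as a covariate. Single ages gave 53, or 7 with DESeq2, counting only contrasts with 2 pools of each genotype in the library (none at 2 weeks). Interval genes passing were 2 in all lymphoid cells and 0 in NK-like cells, which are fewer. The test of the 2-week libraries passed for 1103, with a spread from 1 pair of pools, or 153 with the spread of pools of all ages, and these libraries also differ in genotype and sex. For these too the cause was not tested.

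Lists passing camera were 93 along age and 50 by genotype (143 in all), and 8, 7 and 15 with an estimated correlation. Shares by age passed in 2 classes, in 3 with cells without a hashtag added (NK-like cells beside them), in 1 as shares of all cells, and in 0 to 0 by Spearman with 1 library left out, where 6 libraries can hardly pass over 12 classes. By Pearson r both classes passed without library A or B of 2 weeks. Shares by genotype passed in 0 classes under each of the 4 alternatives, including the threshold used in the first run (at least 50 lymphoid cells per pool), which was then replaced by the planned one. E16 genes outside the postnatal range were 4583, or 4507 with TMM.

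Directions reversed in 6 cases, counting only those where the main or the alternative value passed. Along age these were in ILC3-like cells Stmn1 (0.40 without 1 week, range -1.94 to 0.40 with 1 library left out) and Apoe (0.25 with cells without a hashtag), in NKT-like cells Gzmb (0.0746 without scrublet doublets), and in the Gzmc cluster Ifitm3 (0.60 without 1 week, range -2.36 to 0.60) and Ifitm1 (0.92 without 1 week, range -4.62 to 0.92). By genotype it was Ifitm1 in ILC3-like cells (0.16 without E16, range -5.75 to 0.16). The setting without scrublet doublets also took the largest-hashtag rule. The cause was not tested.

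Without the library as covariate (no replicate block) 0 genotype differences passed. No paired analysis was possible for age because only 2 weeks has more than 1 library, and replicate numbers there pair nothing across ages. No NKT-like class formed under the looser filter, at resolution 0.5 or with cells without a hashtag, and no Gzmc cluster at resolution 0.5, so these have no value. The number of cells limits E16 (173 lymphoid cells) and ILC3-like cells at 6 weeks (8), and depth limits genes near 1 CPM such as Ndn (1.48 CPM in WT).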

Other observations

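The test with sex as a covariate was chosen only after the results had been seen.

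Other biology lies outside the comparisons above. In the Zbtb16 cluster 5 of 14 tissue residency genes rose (Rgs1 0.86, Cd69 0.89, Itga1 0.76 and Zfp683 0.61 per doubling of age) and 2 of 13 circulation and naive genes fell (Igfbp4 and Klf2 -0.71), and neither list passed with an estimated correlation (adjusted p = 0.208 and 0.498 by camera). In the same span H2-Q7, an MHC class I gene, rose in CD4 T-like cells (0.97), NKT-like cells, proliferating cells and the Zbtb16 cluster (1.14).

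Ifitm1 was higher in young libraries in several classes. It fell with age in the Gzmc cluster (-2.75) and in proliferating cells (-3.51), and at E16 it was 296 CPM in ILC3-like cells and 1129 CPM in proliferating cells. In ILC3-like cells the E16 value was carried by the WT pools (15q dup 6.82 log2 lower). With sex as a covariate Ifitm1 differed by sex in all 3 classes, but not in 1 direction. Male over female was 2.50 log2 in ILC3-like cells, -2.38 in proliferating cells and -2.56 in the Gzmc cluster. Ifitm1 thus also differed between pools of the same library, and its link to age is not separated from such differences. As noted above, its slope in the Gzmc cluster turned to 0.92 without the 1-week library, so the fall there rests on that library.

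Cells counted as NKT-like by marker UMIs made up 29.5% of lymphoid cells at E16 and 11.0% at 6 weeks, and 9.83% and 7.01% after every cell was thinned to 1500 UMIs, so much of that difference went with depth.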
